A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

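Total RNA from frozen cell pellets of steady-state chemostats on minimal medium was biotin-labelled and hybridised to Affymetrix yeast arrays, 1 sample per array, per the labels' protocols. The 24 arrays fall into 8 groups of 3, formed by strain (reference or snf1 mutant), limiting nutrient (carbon or nitrogen) and the level of inositol and choline (low or high); the amounts behind low and high are not given in the sources used here. Arrays were grouped by title. For 6 arrays of the snf1 mutant whose title carries the letter N, the description repeats the C-limited text; they were taken as N-limited. The nitrogen-repressed gene DAL5 lies at 10.85 to 11.72 on these 6 arrays and at 11.31 to 11.97 on the N-limited reference arrays, against 6.83 to 7.13 on the 12 C-limited arrays, so their values are those of N-limited arrays. The letter N at the start of a title marks the low level, as the descriptions state.

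The values are the deposited log2 expression values of 10928 probe sets, summarised by the authors with PLIER, per the submitters' processing notes; the version, the background step and the normalization between arrays are not given in the sources used here. That they are on a log scale was read from their range, 4.82 to 13.25. Base 2 is stated nowhere and was assumed, because natural logs would put the brightest probe sets beyond the range of a scanner; every fold below rests on it. The medians of the 24 columns over all probe sets lay between 5.93 and 6.00, and no further scaling was applied. Values near the background may be compressed, which would understate the folds of dim genes. This was not tested.

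The annotation table gave 7244 probe sets 1 gene symbol, 1 probe set several, and did not list 3683. Through gene identifiers 5498 probe sets matched Saccharomyces cerevisiae, and 12 symbols were updated. The probe set with the highest mean was kept for each of the 47 genes with several, which left 5449 genes for testing. The array also carries probe sets for Schizosaccharomyces pombe, and 1747 named probe sets without a S. cerevisiae gene served as background. The 95th percentile of their means, 5.60, was the dim level, and 276 tested genes had a mean below it. For folds the floor was the same percentile taken on each array, 5.56 to 5.63. Some genes were below it on every array of 1 group only. Their fold is given as at least the ratio of the brighter mean to the floor of the dimmer group. Near-identical genes share probe sets: HXT6 and MAL12 were not measured apart from HXT7 and MAL32.

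One linear model with a mean per group was fitted to the 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual and 18.77 total degrees of freedom), so that all groups share one estimate of the spread per gene. From it came 12 differences between pairs of groups and 4 interactions. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 5449 genes. For 31 gene lists (496 tests over the 16 comparisons) camera compared each list's shift with that of other genes at a preset correlation of 0.01 between genes, and was run again with an estimated correlation; adjusted p-values of lists are over the lists of one comparison. It called 195 tests at the preset value and 75 with the estimated one, all 75 among the 195. The rotation test fry, which asks whether a list moves at all, called 252. Counts of list members were also adjusted over the list alone.

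The groups, the tests, the lists, the alternatives and the naming of genes were set before the data were examined. The genes that may be named are 16 fixed ones (SNF1, INO1, CHO1, CHO2, OPI3, ITR1, HNM1, ACC1, FAS1, FAS2, OLE1, ADR1, CAT8, GAP1, HXT1 and HXT7), the 5 largest rises and 5 largest falls of each pair of groups among called genes whose arrays do not overlap, the 5 smallest adjusted p-values in each direction of each interaction, and up to 4 members of each list and comparison with the smallest adjusted p. The plan said 4 in either direction, which was read as 4 among the rises and 4 among the falls.

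The planned test allowed for linear values with a pseudocount; the values are already logs, so none was added. Alternatives tried were quantile normalization, centring on the median, leaving out dim genes, only the arrays compared, the replicate number as a block, a trended and robust moderation, all probe sets, leaving out the arrays whose labels disagree, and leaving out each array in turn. Added after the control probe sets were seen were leaving out the pair of arrays with the lowest 5' signal, a covariate of 3' minus 5' signal, and further fits with a block. Whether replicate numbers pair the arrays was checked from the deviations from the group means. Same-numbered arrays correlated above 0.1 in all 3 pairs for 6 of 28 pairs of groups. Of these, 3 are compared directly: reference and snf1 under N limitation at the high level (r over genes 0.901, 0.784 and 0.868) and at the low level (0.165, 0.313 and 0.405), and snf1 at the low level between C and N limitation (0.173, 0.461 and 0.392). The other 3 meet only in interactions: N-limited reference and C-limited snf1, both low (0.353, 0.526 and 0.491), C-limited high and N-limited low reference (0.270, 0.289 and 0.261), and C-limited high reference and C-limited low snf1 (0.164, 0.135 and 0.155). Arrays of unlike number correlated as well, up to 0.671 in the N-limited high pair and 0.392 between C-limited reference and N-limited snf1, both low. How many of the 28 would pass by chance was not estimated, so pairing at the low level is uncertain. The 3 direct comparisons were taken as paired by number, a reading from the data since no label says what the number marks.

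The procedure was tested on simulated data in which 66 of 5449 genes changed by 0.5, 67 by 1 and 67 by 2 on the log2 scale. For the C-limited reference pair it recovered 81.8% of the changes of 0.5 and 98.5% of those of 1, with 10 false calls. For the interaction of strain and inositol-choline under C limitation the shares were 62.1% and 80.6%, with 6 false calls. The simulated noise was normal, independent and of the same SD on all arrays. Real replicates differed with an SD over genes of 0.06 to 0.52, depending on the group. The simulation therefore cannot show how the shared estimate of the spread behaves on these arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Scanner files were not used here.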

Results

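Transcript levels were measured on 24 arrays of Saccharomyces cerevisiae grown to steady state in chemostats, to capture the response to the level of inositol and choline and to deletion of SNF1, the catalytic subunit of the yeast AMP-activated kinase, under carbon (C) or nitrogen (N) limitation. Inositol and choline are precursors of phosphatidylinositol and phosphatidylcholine. Each of the 8 groups has 3 arrays, and their number limits the precision. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Errors after ± are standard errors of log2 differences from limma, with n = 3 arrays per group throughout. They rest on the spread shared by all 8 groups. Where a gene list has only one pair of counts, the counts adjusted over the list alone were the same.

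The deleted gene was examined on every array. SNF1 lay between 4.95 and 5.02 (log2) on the 12 arrays of the mutant, under the background level of 5.60, and between 7.09 and 8.47 on the 12 reference arrays. Its fall passed the test in all 4 strain comparisons, with the reference at least 5.44-fold and 6.31-fold higher under C limitation (low and high inositol-choline) and at least 5.7-fold and 4.75-fold higher under N limitation. In the last of these the adjusted p was 0.0828 when only the 6 arrays compared were fitted. Probe sets of Schizosaccharomyces pombe, which have no target in these samples, gave between 0 and 10 calls of 1747 in the 16 comparisons by the same limma test.

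Array quality differed. Group means of the spiked control dap were 5.97 to 6.15 (log2) at low and 6.81 to 7.49 at high inositol-choline. Single arrays overlapped, with 6.41 on the highest low and 6.15 on the lowest high array. For the spiked control bioB the group means were 6.44 to 6.64 and 6.82 to 7.78. Handling may therefore differ with the level, and in the responses to inositol-choline the effects of both cannot be told apart. The 3' minus 5' signal of 7 control genes averaged 0.48 to 0.68 (log2) on the 12 arrays at low inositol-choline and 0.69 to 2.68 on the 12 at the high level, with the largest values, 2.67 and 2.68, on replicate 1 of the reference and of the snf1 mutant under N limitation at the high level. Replicates of those N-limited groups differed from one another with an SD over genes of up to 0.52 and 0.49, against 0.06 to 0.15 in the remaining groups. Because all groups share one estimate of the spread, this can move the counts of every comparison. That estimate tends to be too small for the N-limited high groups and too large for the remaining ones. Standard errors and p-values then tend to be too small in comparisons with those groups and too large in the others. Some of the values under other settings are given beside the results and the rest in the part on other settings. Without the pair with the largest values, called members grew by over 1.5 times in 271 of 496 list results and fell by as much in 1.

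**Figure D1:**
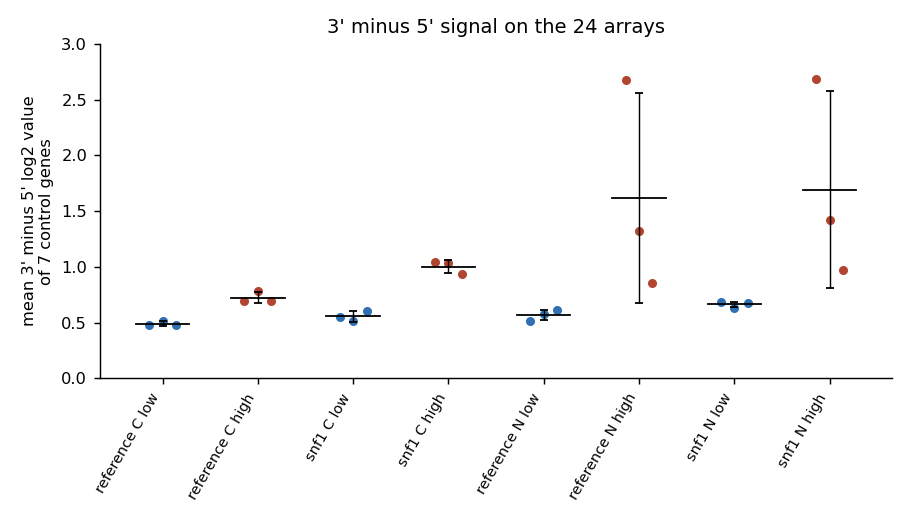
Mean 3' minus 5' log2 value of 7 control genes on each of the 24 arrays, by group, with the group mean and SD (n = 3; blue low, red high inositol-choline). All 12 low arrays sit between 0.48 and 0.68, and replicate 1 of both N-limited high groups sits at 2.67 and 2.68.

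**Figure D2:**
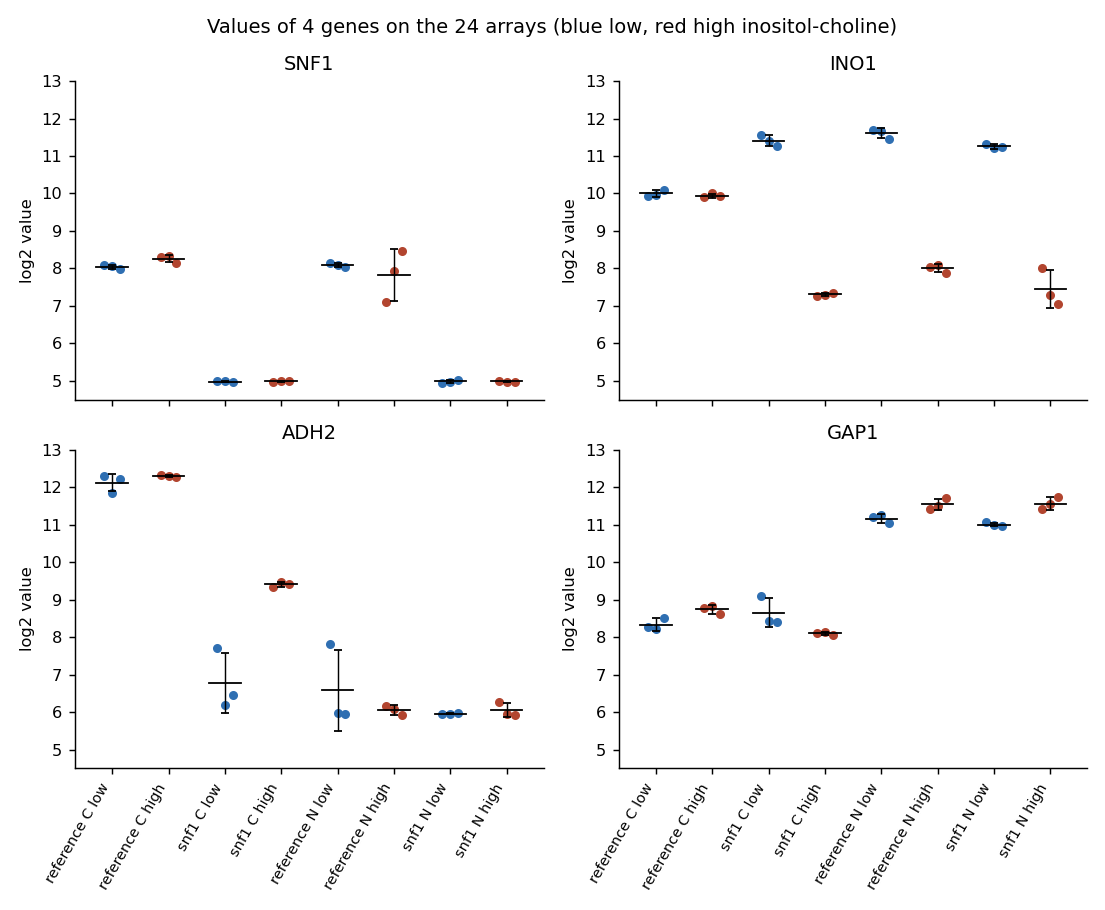
Log2 values of SNF1, INO1, ADH2 and GAP1 on each of the 24 arrays, by group, with the group mean and SD (n = 3; blue low, red high inositol-choline). SNF1 is at background in the 4 snf1 groups, and INO1 stays between 9.91 and 10.10 in the C-limited reference groups.

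The response to inositol-choline was taken within each strain and limitation, as the high minus the low level. In the C-limited reference strain INO1, which encodes inositol-phosphate synthase and is classically repressed by inositol, did not pass the test: its log2 difference was -0.06 ± 0.155 (adjusted p = 0.841), with all 6 arrays between 9.91 and 10.10. CHO1, the phosphatidylserine synthase gene, was 1.23-fold lower (adjusted p = 0.0074), while FAS1, the beta subunit of fatty acid synthase, was 1.31-fold higher (log2 difference 0.39 ± 0.057). OPI3 and CHO2, which methylate phosphatidylethanolamine, had differences of -0.26 and 0.19 and were not called, though OPI3 was on these 6 arrays alone (adjusted p = 0.00797) and CHO2 without the pair of arrays with the lowest 5' signal. The inositol transporter gene ITR1 was at 0.00. The largest rises were those of the mannoprotein gene HPF1, 1.62-fold, and of RLI1 and ARB1, which encode ATP-binding proteins acting on ribosomes, 1.53-fold and 1.52-fold. ADY2, the acetate transporter gene, fell by 0.51 ± 0.123 on the log2 scale, and TSA2, a peroxiredoxin gene, was 1.4-fold lower.

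Among 52 genes of ribosome biogenesis 15 rose (17 adjusted over the list alone) and 37 were not called, with RRP12 at 0.37 and UTP8 at 0.48; camera gave an adjusted p of 6.3e-08, and the adjusted p was 0.42 with an estimated correlation. Of 34 genes of the methyl cycle and sulfur metabolism 4 rose (7 with 1 fall, adjusted over the list alone), among them MET10 at 0.34 (camera adjusted p = 0.014, but adjusted p = 0.73 with an estimated correlation). The 27 phospholipid genes held 2 rises and 4 falls, and 4 rises and 12 falls without the pair of arrays with the lowest 5' signal, which is not part of this comparison. In all 807 of 5449 genes were called, 428 higher and 379 lower, with 1587 at an unadjusted p under 0.05. The count was 1863 with only these 6 arrays fitted and 2623 without the pair of arrays with the lowest 5' signal. Without replicate 2 or 1 of the high group it was 253 or 361, and without replicate 2 of the low group 402.

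In the N-limited reference strain INO1 was 12.1-fold lower at high inositol-choline (log2 difference -3.60 ± 0.155, adjusted p = 1.58e-11), CHO1 1.94-fold lower (-0.95 ± 0.069), OPI3 lower by a log2 difference of -0.72 ± 0.098 and ITR1 by -0.62 ± 0.085. Altogether 13 of the 27 phospholipid genes with control by Ino2 and Ino4 fell and 14 were not called (camera adjusted p = 1.9e-07, and 0.0066 with an estimated correlation). The choline transporter gene HNM1 was not called at -0.44, and its difference was 0.23 with 3' minus 5' signal as a covariate. ACC1, acetyl-CoA carboxylase, was lower by a log2 difference of -0.31. On these 6 arrays alone ACC1 (adjusted p = 0.06) and ITR1 (0.064) were not called, and with the replicate number as a block on them CHO1 (0.0588) and OPI3 (0.15) were not either. The largest rise was that of DIP5, the dicarboxylic amino acid permease gene (5.7-fold), followed among named transporters by HXT7, a high-affinity glucose transporter gene whose probe set cannot be told from HXT6 (3.02-fold).

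Mating genes fell as well: 16 of 27 fell and 1 rose (16 and 2 adjusted over the list alone; camera adjusted p = 2.1e-07, and 3.9e-04 with an estimated correlation). MF(ALPHA)1, the alpha-factor gene, was 9.4-fold lower, AGA1, the agglutinin anchor gene, fell by 1.43 and PRM1 by 1.04. The small heat shock gene HSP26 was 3.74-fold lower (-1.90 ± 0.369), but its difference was -0.88 with 3' minus 5' signal as a covariate, and it was not called on these 6 arrays alone (adjusted p = 0.066). Of 24 genes of beta-oxidation and peroxisomes 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.00102, adjusted p = 0.096 with an estimated correlation). Hexose transport held 6 rises and 1 fall among 18 genes (adjusted p = 0.00396, but adjusted p = 0.18 with an estimated correlation). Reserve carbohydrate genes rose in 7 of 21 cases, the glycogen phosphorylase gene GPH1 by 0.69 (adjusted p = 0.00396, but adjusted p = 0.82 with an estimated correlation). Of 5449 genes 1714 were called, 904 higher and 810 lower, 9 and 30 of them by 2-fold or more. The 3' minus 5' value was 0.52 to 0.61 on the low arrays and 0.85 to 2.67 on the high ones; fitted on these 6 arrays alone the count was 140, and 14 with the replicate number as a block. It was 1119 without replicate 3 of the low group and 1127 without its replicate 1. Without the pair of arrays with the lowest 5' signal 16 phospholipid genes fell and 2 rose, and 17 mating genes fell and 2 rose.

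**Figure D3:**
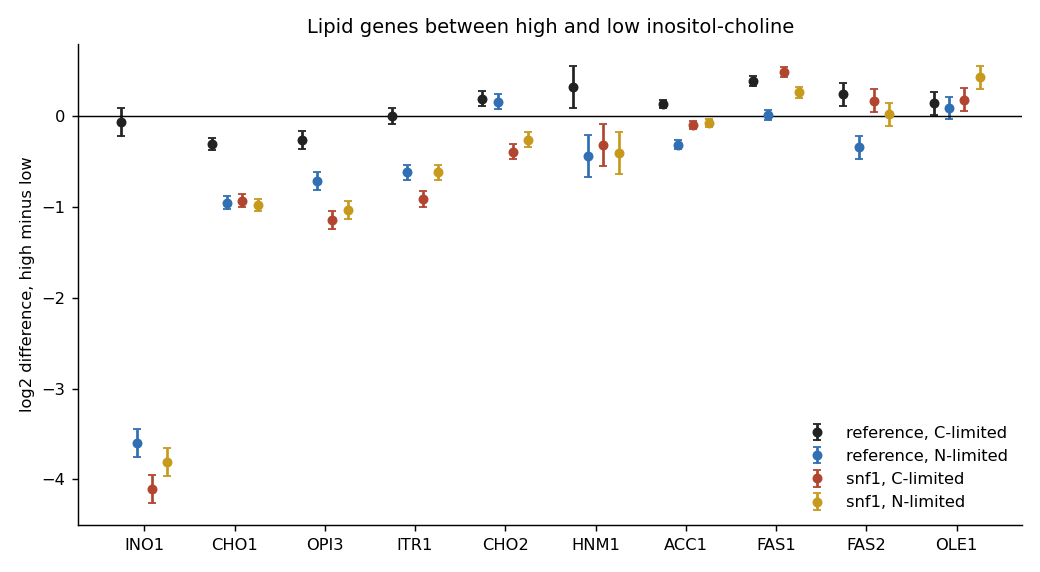
Log2 difference, high minus low inositol-choline, of 10 lipid genes in the 4 combinations of strain and limitation, with standard errors from limma (n = 3 arrays per group). INO1 is at -0.06 in the C-limited reference strain and between -3.60 and -4.11 in the other 3 combinations.

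In the C-limited snf1 mutant INO1 was 17.2-fold lower at high inositol-choline (log2 difference -4.11 ± 0.155, adjusted p = 4.73e-13), OPI3 2.21-fold, CHO1 1.9-fold and ITR1 1.88-fold lower. Of the 27 phospholipid genes 15 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 1.2e-07, and 0.0053 with an estimated correlation). Sterol genes moved the other way: 16 of 25 ergosterol genes rose and 9 were not called, among them ERG11 by 1.12, ERG7, lanosterol synthase, by 1.11 and ERG25 by 0.97 (camera adjusted p = 2.1e-15, and 0.0053 with an estimated correlation). FAS1 was 1.41-fold higher. In the beta-oxidation and peroxisome list 14 genes fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 1.6e-09, and 0.0048 with an estimated correlation): CRC1, the mitochondrial carnitine carrier gene, was 8.55-fold lower, and POT1, the peroxisomal thiolase gene, fell by 1.98.

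The largest rises were in FDH1, formate dehydrogenase (8.29-fold, log2 difference 3.05 ± 0.167), and ADH2, the glucose-repressed alcohol dehydrogenase (6.17-fold, 2.63 ± 0.371). ADH2 was at 7.70 on replicate 1 of the low group against 6.18 and 6.46 on its other replicates. Besides INO1 and CRC1, the largest falls were those of FIT2 (8.81-fold) and FIT3 (7.62-fold), cell wall proteins of siderophore iron uptake, and of EEB1, an ethyl ester synthase gene (5.83-fold). Of 26 iron genes 16 fell and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 6.0e-07, but adjusted p = 0.22 with an estimated correlation). Gluconeogenesis and the glyoxylate cycle held 8 falls and 4 rises among 20 genes (10 and 4 adjusted over the list alone; adjusted p = 0.025, and 0.19 with an estimated correlation), with ICL1, isocitrate lyase, at -2.17 and MLS1, malate synthase, at -1.85. In all 1274 genes were called, 556 higher and 718 lower, 21 and 32 by 2-fold or more. The 3' minus 5' value was 0.51 to 0.61 on the low and 0.93 to 1.04 on the high arrays. The count was 3301 on these 6 arrays alone.

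In the N-limited snf1 mutant PHO84, the high-affinity phosphate transporter gene, was 12.8-fold lower at high inositol-choline (log2 difference -3.68 ± 0.068), next to INO1 at 14-fold (-3.81 ± 0.155, adjusted p = 2.15e-12). OPI3 was 2.04-fold lower, CHO1 1.97-fold and ITR1 1.53-fold, and 16 of 27 phospholipid genes fell with 11 not called (19 adjusted over the list alone; camera adjusted p = 6.3e-08, and 0.0060 with an estimated correlation). The list of the unfolded protein response, which includes INO1, held 15 falls among 26 genes (16 adjusted over the list alone; camera adjusted p = 2.5e-09, and 0.0014 with an estimated correlation): SIL1, a nucleotide exchange factor of the endoplasmic reticulum, was 3.61-fold lower and ULI1 2.86-fold. Among 19 phosphate genes 7 fell and 2 rose (10 and 2 adjusted over the list alone; adjusted p = 0.0040, and 0.034 with an estimated correlation), VTC3 by 1.05 and SPL2 by 1.01.

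Rises were led by DIP5 (5.36-fold), YDR524W-C (3.34-fold), HPF1 (2.81-fold), HXT7 (2.73-fold, shared with HXT6) and MLS1 (2.62-fold). Respiratory chain genes rose in 18 of 38 cases (camera adjusted p = 0.0040, and 0.034 with an estimated correlation), with NDE1, external NADH dehydrogenase, at 0.72. Reserve carbohydrates held 14 rises and 1 fall among 21 genes (15 and 1 adjusted over the list alone; adjusted p = 8.3e-06, but adjusted p = 0.21 with an estimated correlation), GPH1 rising by 1.19. In turn 54 of 128 ribosomal protein genes fell while 4 rose (56 and 5 adjusted over the list alone; adjusted p = 6.0e-06, but adjusted p = 0.47 with an estimated correlation). The 2026 genes called comprised 1062 higher and 964 lower, 15 and 32 by 2-fold or more. The 3' minus 5' value was 0.63 to 0.68 on the low and 0.98 to 2.68 on the high arrays; the count was 738 on these 6 arrays alone and 10 with the replicate number as a block, under which CHO1, OPI3, ITR1 and GPH1 were not called. Without the pair of arrays with the lowest 5' signal 19 genes of the unfolded protein list and 18 of the phospholipid list fell, with 3 rises in the latter.

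Under C limitation 215 genes were called higher and 237 lower at high inositol-choline in both strains, and under N limitation 662 and 560. The high arrays of both strains share lower 5' signal, so no count for independent lists is set beside these.

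Deletion of SNF1 was then compared with the reference strain within each medium. Under C limitation at low inositol-choline the falls in the mutant were led by ADH2, 40.6-fold lower (log2 difference -5.34 ± 0.371). ADH2 was at 7.70 on mutant replicate 1 against 6.18 and 6.46 on the other replicates. The hydrophilin genes GRE1 and SIP18 were 35.5-fold and 20.3-fold lower, RGI2, a gene of respiratory growth, 23.5-fold, and FDH1 21.5-fold. Of 30 general stress genes 29 fell (camera adjusted p = 7.2e-29, and 0.0033 with an estimated correlation), including the chaperone gene SSA3 at -3.45. Of 20 genes of gluconeogenesis and the glyoxylate cycle 16 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 1.3e-14, and 3.1e-04 with an estimated correlation), with JEN1, the lactate transporter gene, at -2.64, ACS1, acetyl-CoA synthetase, at -2.38 and FBP1, fructose bisphosphatase, at -2.12. CAT8, the activator of gluconeogenic genes, was 1.46-fold lower, while ADR1, another activator, was at -0.01 and not called (adjusted p = 0.974).

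INO1 was higher in the mutant, 2.66-fold (1.41 ± 0.155, adjusted p = 5.46e-07), ITR1 1.85-fold, CHO1 1.67-fold, OPI3 1.57-fold and CHO2 1.43-fold. In the phospholipid list 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 7.2e-04, but adjusted p = 0.052 with an estimated correlation). FAS1 was 1.46-fold lower, and 13 ergosterol genes fell against 3 that rose (14 and 3 adjusted over the list alone; adjusted p = 1.5e-05, and 0.089 with an estimated correlation). EEB1 rose 8.57-fold, FIT2 7.2-fold and PHO84 6.67-fold. Mating genes rose in 15 of 27 cases, MFA2 and MFA1, which encode a-factor, by 1.61 and 1.31 (camera adjusted p = 1.9e-05, and 0.0018 with an estimated correlation), and phosphate genes in 10 of 19 with 1 fall (12 and 1 adjusted over the list alone; 0.00126, and 0.025 with an estimated correlation). The list of the Snf1 complex and its partners, which includes the deleted gene, held 10 falls and 4 rises without SNF1 (adjusted p = 0.032, but adjusted p = 0.059 with an estimated correlation); REG2 was at -1.34 and SIP2, a kinase subunit, at -0.82. Iron genes held 18 rises and 1 fall (6.2e-06, but adjusted p = 0.21 with an estimated correlation), and reserve carbohydrates 15 falls and 1 rise (16 and 1 adjusted over the list alone; 2.9e-09, but adjusted p = 0.052 with an estimated correlation). Of the 1877 genes called 1100 were higher and 777 lower, 49 and 171 by 2-fold or more. The count was 3018 on these 6 arrays alone.

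At high inositol-choline under C limitation INO1 was instead 6.23-fold lower in the mutant (log2 difference -2.64 ± 0.155, adjusted p = 5.84e-11). INO1 was between 9.91 and 10.10 on the C-limited reference arrays of both levels. Its strain differences under C limitation, and those between limitations in the reference strain, rest on these arrays, whose level is weighed further below. CHO1 at 0.11 and OPI3 at -0.24 were not called, though OPI3 was on the 6 arrays compared alone (adjusted p = 0.00141). SPS100, a spore wall gene, was 22.1-fold lower, GRE1 19.4-fold and RGI2 14.1-fold, and ADY2 was at least 12.9-fold lower. Again 29 of 30 general stress genes fell (camera adjusted p = 4.0e-27, and 0.0037 with an estimated correlation), as did 17 of 20 genes of gluconeogenesis and the glyoxylate cycle with 1 rise (4.0e-18, and 8.3e-05 with an estimated correlation), FBP1 by 2.15. Beta-oxidation genes joined them with 19 falls and 1 rise among 24 (camera adjusted p = 5.1e-13, and 4.8e-04 with an estimated correlation): POT1 fell by 1.81 and the carnitine acetyltransferase gene CAT2 by 1.58. CAT8 was 1.7-fold lower, and ADR1 fell by 0.56.

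Higher in the mutant were YJL213W (4.27-fold), ULI1 (3.48-fold), the cell wall genes DSE2 (3.46-fold) and CWP1 (3.14-fold), and PHO84 (3.03-fold). In the unfolded protein list 13 genes rose and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 0.0011, and 0.035 with an estimated correlation), and in the mating list 13 rose and 1 fell (14 and 1 adjusted over the list alone; 3.9e-04, and 0.0037 with an estimated correlation). The Snf1 list without SNF1 itself held 10 falls and 2 rises (0.012, and 0.031 with an estimated correlation), and reserve carbohydrates 16 falls and 1 rise (18 and 2 adjusted over the list alone; 2.9e-10, and 0.035 with an estimated correlation), with GPH1 at -1.43. Alternative sugar genes fell in 7 of 16 cases, MAL11 by 1.51 (0.00435, but adjusted p = 0.062 with an estimated correlation). In all 1789 genes were called, 981 higher and 808 lower, 40 and 166 by 2-fold or more. RNA quality moves with the strain here, with 3' minus 5' values of 0.69 to 0.78 on the reference and 0.93 to 1.04 on the mutant arrays. On these 6 arrays alone the count was 3186. With the low-level strain comparison, which uses other arrays, it shared 695 higher and 593 lower genes.

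Under N limitation at low inositol-choline 530 genes differed between the strains, 257 higher and 273 lower, 15 and 9 by 2-fold or more. PHO84 was 14.3-fold higher in the mutant (log2 difference 3.84 ± 0.068), the secreted acid phosphatase gene PHO5 at least 1.83-fold, YET2, an endoplasmic reticulum gene, 3.45-fold, and ULI1 3.11-fold. The low-affinity glucose transporter gene HXT1 was 2.57-fold higher and HXT7 2.8-fold lower (shared with HXT6). INO1 was at -0.34 and not called (adjusted p = 0.214), though it was on these 6 arrays alone (0.00124), CHO1 fell by 0.30 and CHO2 rose by 0.41. MF(ALPHA)1 was 3.58-fold, GPH1 2.52-fold and MLS1 2.49-fold lower.

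The unfolded protein list rose in 17 of 26 genes (18 adjusted over the list alone; camera adjusted p = 5.1e-19, and 1.0e-05 with an estimated correlation), with SIL1 at 1.27, MPD1, a disulfide isomerase gene, at 0.91 and the ER isomerase gene FPR2 at 0.65. Respiratory chain genes fell in 17 of 38 (27 adjusted over the list alone; 1.1e-15, and 6.9e-06 with an estimated correlation), INH1, the ATP synthase inhibitor, by 0.59, and 6 of 19 phosphate genes rose (10 adjusted over the list alone; 2.0e-09, and 1.3e-04 with an estimated correlation). Mating genes fell in 8 of 27 (9 adjusted over the list alone; 1.1e-06, and 2.7e-04 with an estimated correlation). Tricarboxylic acid cycle genes fell in 7 of 21 (13 with 1 rise, adjusted over the list alone), MDH1 by 0.54 (2.1e-07, but adjusted p = 0.082 with an estimated correlation). The 3 list calls lost with the replicate number as a block were ergosterol (adjusted p = 0.0411, then 0.209), gluconeogenesis (0.0411, then 0.146) and the Snf1 list (0.0265, then 0.0509), which without SNF1 itself was not called to begin with (adjusted p = 0.107). With an estimated correlation the 3 lists were not called either (adjusted p = 0.51, 0.26 and 0.052). Values of 3' minus 5' signal also part the strains, 0.52 to 0.61 on the reference and 0.63 to 0.68 on the mutant arrays. The count of genes was 2503 on these 6 arrays alone, 2781 with the block and 1551 without the pair of arrays with the lowest 5' signal, which is not part of this comparison. Without that pair 34 respiratory chain genes fell, 18 mating genes fell and 1 rose, and 16 tricarboxylic acid cycle genes fell and 2 rose.

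At high inositol-choline under N limitation 226 genes were called, 118 higher and 108 lower, 6 and 7 by 2-fold or more. HXT1 was 3.64-fold higher in the mutant, the transketolase gene TKL2 2.56-fold and CTT1, cytosolic catalase, 2.08-fold. Lower were HXT7 (3.1-fold), the maltase gene MAL32 (2.96-fold, shared with MAL12), HXT4 (2.65-fold) and the hexokinase gene HXK1 (2.49-fold). INO1 was lower by a log2 difference of -0.56 ± 0.155 (adjusted p = 0.0492), OPI3 by -0.41 and CHO1 by -0.33. Respiratory chain genes fell in 4 of 38 (6 adjusted over the list alone; camera adjusted p = 1.9e-08, and 3.7e-04 with an estimated correlation). Rises came in 7 of 32 cell wall genes (12 with 1 fall, adjusted over the list alone; 6.7e-08, and 0.0073 with an estimated correlation), CWP1 at 0.73 and the kinase gene SLT2 at 0.37, and in 6 of 27 mating genes (7 adjusted over the list alone; 1.7e-05, and 0.0014 with an estimated correlation). General stress genes held 9 rises and 1 fall (16 and 1 adjusted over the list alone; 2.4e-12, but adjusted p = 0.056 with an estimated correlation).

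This result depended on the arrays fitted. The 2 groups share low 5' signal by replicate number (2.67 and 2.68 in replicate 1); the count was 5 on these 6 arrays alone, 527 without replicate 1 of both groups, 214 with the number as a block on these arrays and 1035 with the block in the fit of all arrays. Leaving out replicate 1 of the reference alone gave 400, and of the mutant alone 357. Of the 10 leading genes 4 were called on the 6 arrays alone and all 10 without replicate 1; INO1, CHO1 and OPI3 were not called on the 6 arrays alone. Under the block the lists of alternative sugar use (adjusted p = 0.0137, then 0.0719) and phosphate (0.0149, then 0.142) lost their call; with an estimated correlation they were not called either (adjusted p = 0.13 and 0.074). Across the low and high levels, which use different arrays, 45 genes were higher and 62 lower in both. Both comparisons draw on the same estimate of the spread per gene, so no count for independent lists is set beside these.

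**Figure D4:**
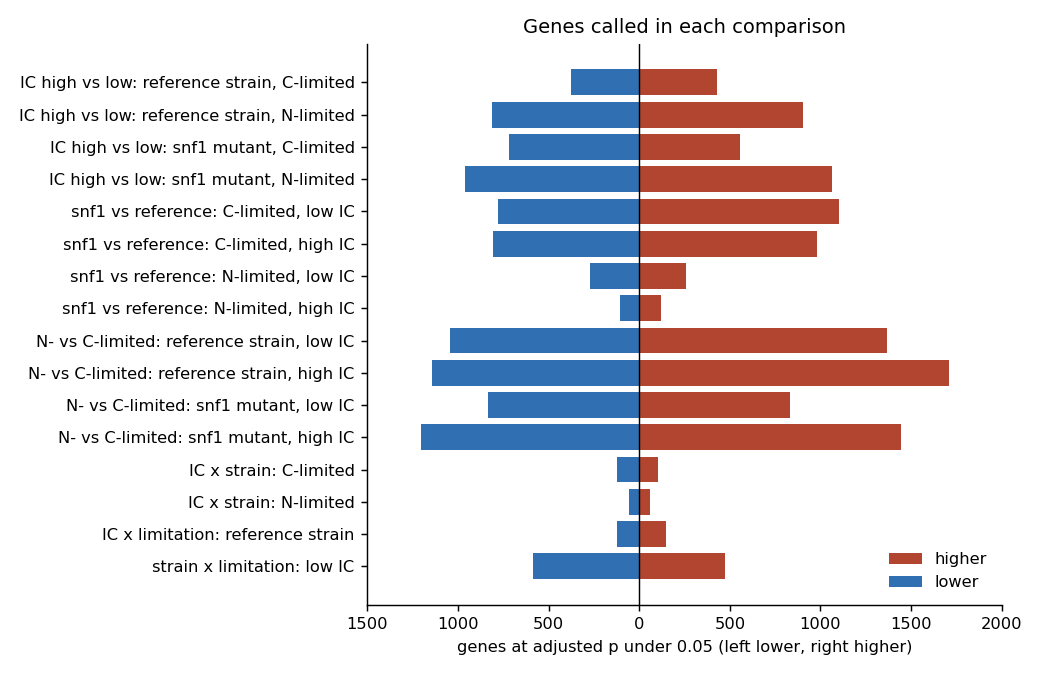
Number of genes at an adjusted p under 0.05 (limma, 5449 genes, n = 3 arrays per group) in each of the 16 comparisons, lower to the left and higher to the right; IC stands for inositol-choline. The strain comparisons hold 1877 and 1789 genes under C limitation and 530 and 226 under N limitation.

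The limiting nutrient was compared within each strain and level. In the reference strain at low inositol-choline the rises under N limitation were led by the oligopeptide transporter gene OPT2, at least 54.3-fold higher, and included DAL80, a GATA repressor gene, 22.7-fold, DAL5, the allantoate permease gene, 20.8-fold (log2 difference 4.38 ± 0.069) and GAP1, the general amino acid permease gene, 7.12-fold. HXT1 was at least 8.12-fold higher and HXT7 5.76-fold lower (shared with HXT6). The falls were led by ADH2 (46.5-fold), RGI2 (45.6-fold), GRE1 (42.7-fold) and SIP18 (32.3-fold). ADH2 was at 7.83 on N-limited replicate 1 against 5.97 and 5.95 on the other replicates, and its difference was -6.16 without that array, against -5.54. Of the lipid genes INO1 was 3.03-fold higher (1.60 ± 0.155, adjusted p = 5.52e-08), HNM1 2.84-fold, ITR1 2.22-fold, OPI3 2.14-fold and CHO1 1.98-fold.

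Of 37 nitrogen catabolite repressed genes 25 rose and 6 fell (26 and 6 adjusted over the list alone; camera adjusted p = 1.7e-07, but adjusted p = 0.26 with an estimated correlation). Phospholipid genes rose in 21 cases of 27 and fell in 1 (23 and 1 adjusted over the list alone; 2.4e-07, and 0.0058 with an estimated correlation). Mating genes rose in 24 cases with 1 fall (4.3e-13, and 1.1e-05 with an estimated correlation; AGA1 at 2.73), and cell cycle genes rose in 25 of 31 (26 adjusted over the list alone; 1.9e-06, and 0.013 with an estimated correlation), CLN3, a G1 cyclin gene, at 1.26. Falls came in 28 of 30 general stress genes (9.4e-19, and 0.011 with an estimated correlation) and in 19 of 20 genes of gluconeogenesis and the glyoxylate cycle with 1 rise (9.4e-19, and 3.2e-05 with an estimated correlation; SFC1 at least 19.2-fold lower). Beta-oxidation genes fell in 19 of 24 cases with 3 rises (1.6e-12, and 4.2e-04 with an estimated correlation), and alternative sugar genes in 9 of 16 (2.0e-05, and 0.0095 with an estimated correlation). Respiratory chain genes fell in 13 of 38 with 2 rises (0.0036, and 0.018 with an estimated correlation). Of the 2412 genes called 1369 were higher and 1043 lower, 136 and 216 by 2-fold or more.

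At high inositol-choline the reference strain gave 2850 called genes between limitations, 1709 higher and 1141 lower under N limitation, 127 and 245 by 2-fold or more. INO1 was 3.84-fold lower here (log2 difference -1.94 ± 0.155, adjusted p = 3.12e-09). OPT2 was at least 64.9-fold, DAL5 28-fold, DAL80 17.3-fold and GAP1 6.99-fold higher, and DIP5 at least 13-fold. The difference of DAL80 was 4.11, and 5.06 with 3' minus 5' signal as a covariate. ADH2 was 75.8-fold lower, GRE1 58.6-fold, SIP18 42.1-fold and SPG4, a stationary phase gene, 34.6-fold. Gluconeogenesis held 19 falls and 1 rise among 20 (camera adjusted p = 7.5e-18, and 9.1e-05 with an estimated correlation), and general stress 28 falls among 30 (7.5e-18, and 0.020 with an estimated correlation). Beta-oxidation held 20 falls and 2 rises among 24 (21 and 2 adjusted over the list alone; 3.1e-15, and 1.9e-04 with an estimated correlation) and mating 21 rises and 2 falls among 27 (2.6e-06, and 5.1e-04 with an estimated correlation). Nitrogen catabolite genes rose in 25 of 37 and fell in 7 (2.3e-06, but adjusted p = 0.29 with an estimated correlation), and ribosome biogenesis genes fell in 34 of 52, the nucleolar gene NSR1 by 1.81 (4.8e-08, but adjusted p = 0.063 with an estimated correlation). The 3' minus 5' value was 0.69 to 0.78 on the C-limited and 0.85 to 2.67 on the N-limited arrays; the count was 1598 on these 6 arrays alone and 1031 with the replicate number as a block. With the low level, measured on other arrays, it shared 1062 higher and 768 lower genes.

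In the snf1 mutant at low inositol-choline OPT2 was 36.4-fold higher under N limitation, DAL5 15-fold, DAL80 12.9-fold, PDC5, a pyruvate decarboxylase gene, 10.8-fold and GAP1 5.13-fold. HXT7 was 19.8-fold lower (log2 difference -4.31 ± 0.102; shared with HXT6), FIT2 17.2-fold, CRC1 13.6-fold and PDH1, a gene of propionate use, 10.2-fold. INO1 was at -0.16 and not called (adjusted p = 0.521; 0.0139 with the replicate number as a block on these 6 arrays), and OPI3 rose by 0.36. Respiratory chain genes fell in 32 of 38 cases (34 with 1 rise, adjusted over the list alone; camera adjusted p = 8.7e-19, and 1.8e-06 with an estimated correlation), CYC1, cytochrome c, by 0.97. Of 21 tricarboxylic acid cycle genes 19 fell (20 adjusted over the list alone; 1.0e-13, and 0.0093 with an estimated correlation), MDH1, mitochondrial malate dehydrogenase, by 1.27. Beta-oxidation held 19 falls and 1 rise (20 and 1 adjusted over the list alone; 1.4e-17, and 7.3e-05 with an estimated correlation), and gluconeogenesis 17 and 1 (18 and 1 adjusted over the list alone; 5.3e-14, and 1.1e-04 with an estimated correlation). Among 47 amino acid synthesis genes under Gcn4 28 fell and 1 rose (30 and 1 adjusted over the list alone; 5.0e-10, and 0.027 with an estimated correlation).

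Rises under N limitation came in 24 of 37 nitrogen catabolite genes, with 3 falls (25 and 3 adjusted over the list alone; 6.5e-12, but adjusted p = 0.13 with an estimated correlation), and in 18 of 26 genes of the unfolded protein list (6.7e-08, and 0.0013 with an estimated correlation). They also came in 16 of 27 mating genes (17 adjusted over the list alone; 2.3e-08, and 9.4e-05 with an estimated correlation), in 10 of 19 phosphate genes with 1 fall (1.6e-05, and 0.0021 with an estimated correlation) and in 12 of 31 cell cycle genes (17 adjusted over the list alone; 1.0e-04, and 0.036 with an estimated correlation). Iron genes fell in 18 of 26 with 1 rise (6.7e-08, but adjusted p = 0.13 with an estimated correlation). The 1666 called genes were 833 higher and 833 lower, 51 and 93 by 2-fold or more. Between limitations the 3' minus 5' value was 0.51 to 0.61 on the C-limited and 0.63 to 0.68 on the N-limited arrays. The count was 3425 on these 6 arrays alone and 3626 with the replicate number as a block, under which the hexose transport list lost its call (adjusted p = 0.0443, then 0.0836), as it did with an estimated correlation (adjusted p = 0.23).

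At high inositol-choline the snf1 mutant had OPT2 53.7-fold, DAL5 26.9-fold, DAL80 15.7-fold, MLS1 13.2-fold and GAP1 11-fold higher under N limitation, and HXT1 16.7-fold higher. The difference of DAL80 was 3.98, and 4.71 with 3' minus 5' signal as a covariate. HXT2, a glucose transporter gene, was 11.9-fold lower, FDH1 11.2-fold, ADH2 10.2-fold, ATO2, a putative ammonia and acetate transporter gene, 9.79-fold and JEN1 7.89-fold. INO1 was at 0.14 and not called (adjusted p = 0.470). Amino acid synthesis genes under Gcn4 fell in 35 of 47 and rose in 4 (37 and 4 adjusted over the list alone; camera adjusted p = 1.9e-10, and 0.033 with an estimated correlation), HOM3, aspartate kinase, by 1.41 and TRP4 by 1.33. Falls also came in 30 of 38 respiratory chain genes with 3 rises (33 and 3 adjusted over the list alone; 6.1e-07, and 0.0012 with an estimated correlation), in 19 beta-oxidation genes with 1 rise (2.1e-08, and 0.0033 with an estimated correlation) and in 15 of 20 gluconeogenesis genes with 1 rise (1.4e-06, and 0.0079 with an estimated correlation). In contrast 20 of 27 mating genes rose and 1 fell (5.2e-06, and 0.0012 with an estimated correlation). Ergosterol genes fell in 17 of 25 with 1 rise (19 and 1 adjusted over the list alone; 6.1e-07, but adjusted p = 0.072 with an estimated correlation), and nitrogen catabolite genes rose in 22 and fell in 2 (3.6e-10, but adjusted p = 0.20 with an estimated correlation). In all 2650 genes were called, 1444 higher and 1206 lower, 102 and 120 by 2-fold or more. The 3' minus 5' value was 0.93 to 1.04 on the C-limited and 0.98 to 2.68 on the N-limited arrays; the count was 1656 on these 6 arrays alone and 1156 with the replicate number as a block. It shared 612 higher and 600 lower genes with the low level, measured on other arrays but fitted with the same estimate of the spread per gene.

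Differences between these responses were tested as interactions, each a difference of 2 log2 differences. Under C limitation the response to inositol-choline differed between snf1 and reference for INO1 by -4.05 ± 0.22 (adjusted p = 3.24e-10), for ITR1 by -0.91, for OPI3 by -0.88, for CHO1 by -0.63 and for CHO2 by -0.58. CRC1 differed by -2.92, EEB1 by -2.40 and POT1 by -1.82, whereas FDH1 differed by 2.94, PBI1 by 1.72 and ULI1 by 1.32. The 25 ergosterol genes held 16 with a higher response in the mutant (17 adjusted over the list alone; camera adjusted p = 3.8e-25, and 6.3e-04 with an estimated correlation). The 24 beta-oxidation genes held 10 with a lower one (14 with 1 higher, adjusted over the list alone; 7.1e-19, and 9.5e-05 with an estimated correlation) and the 27 phospholipid genes 9 lower (12 adjusted over the list alone; 7.0e-08, and 0.0049 with an estimated correlation). Iron genes held 10 lower (17 with 1 higher, adjusted over the list alone; 7.1e-13, but adjusted p = 0.059 with an estimated correlation). There were 226 genes in all, 101 higher and 125 lower; on these 12 arrays alone the count was 817, and 837 with the replicate number as a block.

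Under N limitation the same interaction was called for 113 genes, 57 higher and 56 lower. INO1 at -0.21 and CHO1 at -0.03 were not among them (adjusted p = 0.988 and 0.999), though INO1 was at -0.48 and called without replicate 1 of both high groups (0.021). PHO84 differed by -3.31 ± 0.096, ULI1 by -1.45 and MCD4, a gene of glycolipid anchor synthesis, by -1.14, while DDR2, a stress gene, differed by 1.36, AGA1 by 1.29 and PRM1 by 0.96. The unfolded protein list held 11 of 26 genes with a lower response in the mutant (15 adjusted over the list alone; camera adjusted p = 1.5e-23, and 2.4e-06 with an estimated correlation). Under C limitation this list shifted the other way (camera adjusted p = 6.8e-04, and 0.031 with an estimated correlation), with 1 gene called higher and 1 lower. The mating list held 8 of 27 with a higher one (11 adjusted over the list alone; 8.5e-17, and 1.8e-06 with an estimated correlation), and the phosphate list 4 lower (6 with 1 higher, adjusted over the list alone; 1.1e-08, and 2.3e-04 with an estimated correlation). General stress genes held 4 higher (9 adjusted over the list alone; 3.3e-10, but adjusted p = 0.093 with an estimated correlation). The count was 34 on these 12 arrays alone, 33 with the replicate number as a block on them, 640 with the block within the high groups in the fit of all arrays, and 403 without replicate 1 of both high groups. Leaving out single arrays gave 70 (reference, low, replicate 2), 174 (reference, high, replicate 1), 199 (mutant, high, replicate 1) and 172 (mutant, high, replicate 3).

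Between limitations in the reference strain the response to inositol-choline differed for INO1 by -3.54 ± 0.22 (adjusted p = 5.22e-09), for CHO1 by -0.65, for ITR1 by -0.62, for ACC1 by -0.45 and for FAS1 by -0.38, each lower under N limitation, while OPI3 at -0.45 was not called (but -0.55 and called without replicate 1 of both N-limited high groups). ITR1 and FAS1 were not called on these 12 arrays alone. DIP5 differed by 2.49, HXT7 by 1.47 (shared with HXT6), IMD2, an IMP dehydrogenase gene, by 1.44 and RGI1 by 1.20, against -1.68 for AGA1 and -1.33 for FIG2, another mating adhesin gene. Mating genes held 8 lower of 27 (11 adjusted over the list alone; camera adjusted p = 5.1e-11, and 2.7e-05 with an estimated correlation), and phospholipid genes 10 lower and 1 higher (11 and 1 adjusted over the list alone; 4.2e-07, and 0.011 with an estimated correlation). Beta-oxidation genes held 5 lower and 1 higher (9 and 1 adjusted over the list alone; 2.5e-05, and 0.028 with an estimated correlation) and fatty acid synthesis 4 lower of 21 (8 with 1 higher, adjusted over the list alone; 0.0010, but adjusted p = 0.14 with an estimated correlation). Of 269 genes 149 were higher and 120 lower; the count was 111 on these 12 arrays alone, 71 with the replicate number as a block on them and 875 without replicate 1 of both N-limited high groups. Without replicate 3 of the N-limited high group alone it was 575, and without any of 7 other single arrays between 135 and 170.

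The effect of the deletion at low inositol-choline differed between limitations for 1062 genes, 476 higher and 586 lower under N limitation. SPG1 differed by 3.45 ± 0.143, PAU3 by 3.09, FBP1 by 2.07 and MBR1, a gene of mitochondrial function, by 1.87, against -3.37 for EEB1, -2.45 for CRC1 and -1.90 for MFA2. INO1 differed by -1.75 ± 0.22 (adjusted p = 5.69e-06) and CHO1 by -1.04. General stress genes held 29 higher of 30 (camera adjusted p = 3.7e-32, and 0.0014 with an estimated correlation), and gluconeogenesis 14 of 20 (14 with 1 lower, adjusted over the list alone; 6.3e-13, and 2.2e-04 with an estimated correlation). Ergosterol held 11 higher of 25 (1.9e-08, and 0.032 with an estimated correlation) and the unfolded protein list 10 higher and 1 lower (13 and 1 adjusted over the list alone; 7.2e-06, and 0.0055 with an estimated correlation). Lower were 18 of 27 mating genes (19 with 1 higher, adjusted over the list alone; 1.2e-11, and 2.5e-05 with an estimated correlation) and 23 of 38 respiratory chain genes with 1 higher (25 and 1 adjusted over the list alone; 7.1e-09, and 1.7e-04 with an estimated correlation). Phospholipid genes held 12 lower and 1 higher (14 and 1 adjusted over the list alone; 7.5e-05, and 0.026 with an estimated correlation). On these 12 arrays alone the count was 2568, and 2616 with the replicate number as a block.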

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

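Chosen after their results were seen were the 4 tests of other splits with the additive effects removed, the tests of splits that keep or part pairs of same-numbered arrays, and the 3 tests on INO1 in the C-limited reference strain; the other tests were chosen before. The genes below had responses that differed between groups in an interaction test.

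Under C limitation the response to inositol-choline differed between snf1 and reference for 226 genes. In the direction of the mutant the leading differences were INO1 -4.05, CRC1 -2.92, EEB1 -2.40, POT1 -1.82 and MRX3 -1.10, and FDH1 2.94, PBI1 1.72, ULI1 1.32, ATF2 0.96 and ERG7 0.75 (log2). After the additive effects were removed 1 of 100 splits of the 12 arrays, the real one, gave as many genes, with 16 as the highest of the others, a share under 0.05. Without that removal 6 of 100 did, up to 1896, but such splits also carry the effects of strain and medium.

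Under N limitation the same interaction held 113 genes, led by PHO84 -3.31, ULI1 -1.45, MCD4 -1.14, DOG2 -0.92 and FPR2 -0.62, and by DDR2 1.36, AGA1 1.29, PRM1 0.96, YGR109W-B 0.95 and GPG1 0.90. Over all splits drawn chance was not excluded for this count: 8 of 100 gave as many with the additive effects removed, up to 2625, and 12 of 100 without, up to 2040. A count that many times the real one points to a structure of the samples. Of the 10 splits that keep every pair of same-numbered arrays of both strains together, only the real one called genes by limma, the highest other being 0, but 10 are too few for a share under 0.05. With the number as a block within the high groups the count was 640, and 33 with it as a block on the 12 arrays alone.

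Between limitations in the reference strain 269 genes differed in their response, led by INO1 -3.54, AGA1 -1.68, FIG2 at -1.33, PRM1 -1.07 and NRK1 -1.03, and by DIP5 2.49, HXT7 1.47, IMD2 1.44, RGI1 1.20 and USV1 0.78. With the additive effects removed 1 of 100 splits gave as many, the highest other being 4, and without the removal 7 of 100, up to 1098.

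The effect of the deletion at low inositol-choline differed between limitations for 1062 genes, led by SPG1 3.45, PAU3 3.09, ANS1 2.46, FBP1 2.07 and MBR1 1.87, and by EEB1 -3.37, CRC1 -2.45, YJL213W -2.29, MFA2 -1.90 and MRX3 -1.31. With the additive effects removed 1 of 100 splits gave as many, the highest other being 424, and without the removal 7 of 100, up to 1701. These splits take no account of the replicate number. In each interaction the other splits also hold any real interaction in their spread, which lowers their counts. Their highest counts therefore do not measure how many genes chance would call. Same-numbered arrays correlated in some of these groups, such as N-limited reference and C-limited snf1 (0.353, 0.526 and 0.491). Among the interactions, splits that keep such pairs together were run for inositol-choline by strain under N limitation alone.

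A reporter control probe set, outside the genes tested, was at 10.03 on the lowest of the 12 snf1 arrays and at 5.25 on the highest of the 12 reference arrays.

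For the differences between pairs of groups the 10 splits of 6 arrays are too few for a share under 0.05. Every other split also mixes both groups, so a real difference enters its spread and lowers its count. Counts of the other splits therefore do not measure how many genes chance would call. The real counts were 807, 1714, 1274 and 2026 for inositol-choline, 1877, 1789 and 530 for strain (C-limited low and high, N-limited low) and 2412, 1666 and 2650 for limitation (reference low, snf1 low and high). In each of these the highest other split called 0 genes by limma over all arrays, so 1 of 10, the real one, was as large. For limitation in the reference at high inositol-choline the count was 2850 and the highest other 12.

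In the N-limited responses to inositol-choline, the log2 differences of called genes followed the loss of signal on replicate 1 against replicate 3 in the N-limited high group of the other strain, with a Pearson r of 0.59 over 1714 genes (reference) and 0.53 over 2026 (snf1); genes are not independent replicates. Loss of 5' signal may therefore account for part of these counts, which were 140 and 738 on their own arrays. In the C-limited responses r was -0.06 over 807 genes and 0.16 over 1274, which argues against it there. Of the 10 leading genes of each N-limited response, all 10 were called without the pair of arrays with the lowest 5' signal, 9 with the covariate, and 6 (reference) and 9 (snf1) on their own arrays. The level of inositol-choline itself stays open beside it, since every high array has a larger 3' minus 5' value than every low one.

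In the strain comparison under N limitation at high inositol-choline 5 of 10 splits gave at least the 226 genes of the real one, the highest other 3164. The replicate numbers of both groups share array quality, with 3' minus 5' values of 2.67 and 2.68 in replicate 1, and the other splits as large all leave a pair of same-numbered arrays together; of the 4 splits that part all 3 pairs, too few for a share under 0.05, the highest other gave 0 by limma. With the number as a block within these groups the count was 1035, in line with a shared array quality that may hide strain differences. What the number marks is not given in the labels. The strain remains an open explanation for the genes called.

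INO1 was not called between inositol-choline levels in the C-limited reference strain. Arrays exchanged between both groups would spread it by over 2 on the log2 scale, and the 6 arrays spanned 0.20. A loss of 5' signal would shift INO1 by 0.076 by its mean slope on that measure, which argues against it as well. Of 447 genes called in one direction in the other 3 responses 93.3% had that sign here. So did 94.4% of the 89 whose loss of 5' signal goes the other way in both strains, with 34 called in that sign and 0 in the other. Loss of 5' signal does not explain the sign of these 89. Other handling shared by the high arrays could, so the signs cannot decide whether a whole group had the wrong level. What stays open is a whole group with the wrong level together with handling shared by the high arrays, which the labels do not give. A response of the reference strain that depends on the limiting nutrient stays open too, untested beyond the interaction of -3.54. C-limited reference arrays also enter the INO1 differences between strains under C limitation and between limitations in the reference strain. They enter its interactions as well, except inositol-choline by strain under N limitation. These INO1 differences are not separate findings, and the doubt over a group's level passes to each that uses it.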

How the results depend on the processing

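The alternatives added after the data were seen were leaving out the pair of arrays with the lowest 5' signal (replicate 1 of both N-limited high groups), a covariate of 3' minus 5' signal, the block within the N-limited high groups, the block in fits of 2 or of 4 groups and the Snf1 list without SNF1; the rest were planned. Counts of called genes stayed within 1.5 times under quantile normalization, median centring and without dim genes. They also did with the replicate number as a block over all arrays, with trended and robust moderation and with all probe sets. Without the arrays whose labels disagree they did so in the comparisons that do not use those arrays. Comparisons that use them could not be fitted without them, so that setting does not test how those arrays were grouped. Most of the 2543 pairs of a named gene and a comparison were chosen for a call in the main fit, which 2415 had. That most keep their call is therefore partly built in and says little about other genes. Over these pairs and all settings, 42665 of 46086 values stayed on their side of the threshold. The call was lost by 3175 and gained by 240, and 6 changed sign with a call in at least 1 of both fits. Among the 42665 are 97 sign changes, over 35 pairs, of genes called in neither fit; leaving out single arrays accounts for 1779 of the lost calls. Fewer arrays lower the power, but many counts rose on the arrays compared alone where no N-limited high group was used. The SD over genes between replicates of up to 0.52 in the N-limited high groups enters every fit of all arrays. Beyond that, the cause was not tested. Signal over background limits the 276 genes below the dim level of 5.60. Array weights did not converge, so no value is given, and the alternative pseudocount does not apply to values that are already logs.

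With only the arrays compared, the response to inositol-choline gave 1863 (reference, C-limited), 140 (reference, N-limited), 3301 (snf1, C-limited) and 738 (snf1, N-limited) genes. The strain comparisons gave 3018 and 3186 under C limitation (low, high) and 2503 and 5 under N limitation, and the limitations gave 1598 (reference, high), 3425 (snf1, low) and 1656 (snf1, high). Interactions gave 817 (inositol-choline by strain, C-limited), 34 (the same, N-limited), 111 (inositol-choline by limitation) and 2568 (strain by limitation). Without the pair of arrays with the lowest 5' signal the counts in the same order, for those that moved by over 1.5 times, were 2623 (reference, C-limited) and 2907 (snf1, C-limited) for inositol-choline, 3185, 3096, 1551 and 527 for strain, 2917 (snf1, low) for limitation and 914, 403, 875 and 2246 for the interactions. With the covariate they were 2540 and 2826, 3121, 3044, 1428 and 844, 2890, and 755, 497, 875 and 2156. List tests called fell from 195 to 75 with an estimated correlation.

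With the replicate number as a block within the N-limited high groups, inositol-choline gave 2759 (reference, C-limited) and 3019 (snf1, C-limited), strain 3270, 3200, 1654 and 1035, limitation 3656 (reference, low) and 3025 (snf1, low), and the interactions 1032 and 640 (inositol-choline by strain, C- and N-limited) and 2362 (strain by limitation). With the block and only the 2 groups compared, inositol-choline gave 1881, 14, 3253 and 10 in the order above, strain 3222 (C-limited, high) and 2781 (N-limited, low), and limitation 1031 (reference, high), 3626 (snf1, low) and 1156 (snf1, high). With the block and only the 4 groups of an interaction, the counts were 837 and 33 (inositol-choline by strain, C- and N-limited), 71 (inositol-choline by limitation) and 2616 (strain by limitation). Lists called without the block in the 3 comparisons taken as paired by number were 15, 13 and 16 of 31. The comparisons, in order, are strain under N limitation at low and high, and limitation in snf1 at low. The block ended 3, 2 and 1 of these calls, given beside those results. With the lists called in neither fit, 28, 29 and 30 of 31 results stayed on their side of the threshold. In the other comparisons of 2 groups the arrays share only a number. The interactions also hold groups whose same-numbered arrays correlate, and their lists were not fitted with a block.

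With a call in at least 1 of both fits, signs changed for HNM1 in the N-limited reference response (0.23 with the covariate, -0.44 without) and in that of snf1 (0.26, against -0.40), MVD1 in the N-limited reference response (0.071 with the covariate, -0.69 without), and for SNF1 (0.39, against -0.0012) and NEM1 (0.018, against -0.37) in the N-limited snf1 response with the covariate. HXT1 in the N-limited snf1 response was 0.27 without the pair of arrays with the lowest 5' signal, against -0.23. SNF1 is deleted in the mutant and lay between 4.95 and 5.02 on its 12 arrays. Its call with the covariate (limma adjusted p = 0.0456) is therefore false. The slope of the covariate is shared by all groups, so other values with the covariate can be off as well. The cause of the other sign changes was not tested.

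Leaving out 1 array at a time gave ranges of 253 to 963, 1119 to 2313, 906 to 987 and 1515 to 2374 for inositol-choline (reference C- and N-limited, snf1 C- and N-limited). Strain ranged over 1491 to 1802, 1488 to 1565, 360 to 420 and 178 to 400 (C-limited low and high, N-limited low and high), limitation over 2061 to 2193, 2458 to 3113, 1390 to 1433 and 2270 to 2818 (reference low and high, snf1 low and high), and the interactions over 157 to 223, 70 to 199, 135 to 575 and 840 to 1060. Moves of over 1.5 times in the C-limited reference response came without reference C-limited high replicates 2 (253) and 1 (361) and low replicate 2 (402); in the N-limited one without low replicates 3 (1119) and 1 (1127); in the N-limited high strain comparison without reference replicate 1 (400) and snf1 replicate 1 (357). For inositol-choline by strain under N limitation they came without reference low replicate 2 (70) and high replicate 1 (174) and snf1 high replicates 3 (172) and 1 (199). For inositol-choline by limitation they came without C-limited low replicates 2 (135) and 1 (170), C-limited high replicates 2 (145) and 1 (149), N-limited low replicates 1 (141), 2 (153) and 3 (163), and N-limited high replicate 3 (575). With only their own arrays fitted, the 10 leading genes were all called in 13 of 16 comparisons, and 6, 9 and 4 of 10 in the N-limited responses of reference and snf1 and in the N-limited high strain comparison.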

Other observations

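The list tests given here were all planned. Sphingolipid genes rose under N limitation in the reference strain, 14 of 25 at low inositol-choline (camera adjusted p = 0.020, but adjusted p = 0.17 with an estimated correlation) and 12 with 2 falls at the high level (14 and 2 adjusted over the list alone; 0.020, but adjusted p = 0.14 with an estimated correlation). CSH1, a mannosylinositol phosphorylceramide synthase subunit gene, rose by 0.93 ± 0.06 and 1.09 ± 0.06 on the log2 scale, and ISC1, the inositol phosphosphingolipid phospholipase C gene, by 0.79 and 0.95 (n = 3 arrays per group). In the snf1 mutant at low inositol-choline 8 rose (0.011, but adjusted p = 0.13 with an estimated correlation). The ceramide hydroxylase gene SUR2 fell at high inositol-choline by 0.93 in the N-limited reference and by 1.14 in the C-limited mutant. Inositol phosphate and phosphoinositide genes held 11 rises and 2 falls among 22 under N limitation in the reference at low inositol-choline (13 and 2 adjusted over the list alone; 0.041, but adjusted p = 0.15 with an estimated correlation), SAC1, a phosphoinositide phosphatase gene, at 0.53. The storage lipid list was called in no comparison; of its 25 genes 11 rose and 3 fell at high inositol-choline in the N-limited mutant (11 and 4 adjusted over the list alone; adjusted p = 0.31), with the lipase genes TGL4 at 0.45 and TGL1 at 0.36. GUT1, glycerol kinase, fell by 1.45 and 1.80 in the C-limited mutant at low and high inositol-choline.

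Under N limitation vitamin genes fell in the reference strain, 12 of 27 with 5 rises at low inositol-choline (13 and 6 adjusted over the list alone; adjusted p = 0.023, but adjusted p = 0.086 with an estimated correlation) and 14 with 8 rises at the high level (15 and 8 adjusted over the list alone; 0.0086, but adjusted p = 0.062 with an estimated correlation). THI13, of thiamine synthesis (its near relatives THI5, THI11 and THI12 were not measured apart), was at -1.48 and -1.40 and BIO3, of biotin synthesis, at -0.98 and -1.10. Cell wall genes held 14 falls and 6 rises among 32 at the high level (15 and 6 adjusted over the list alone; 7.9e-04, but adjusted p = 0.065 with an estimated correlation), TIR3, a mannoprotein gene, at -2.24 and PIR3 at -2.88. Under N limitation 2 cell wall genes responded higher to inositol-choline in the mutant than in the reference (9 adjusted over the list alone; 1.7e-05, and 0.025 with an estimated correlation). Of 21 meiosis genes 8 fell and 3 rose between limitations in the reference at low inositol-choline (0.046, but adjusted p = 0.40 with an estimated correlation), SPS100 at -4.35 and SPS4 at 2.55. The glycolysis list was called in the interaction of inositol-choline and limitation alone, with 2 of 21 genes lower, TDH1 at -0.43 and PDC6 at -0.76 (0.0086, but adjusted p = 0.56 with an estimated correlation). The zinc list was called in no comparison; under N limitation in the reference at low inositol-choline 8 of 18 rose and 4 fell (9 and 4 adjusted over the list alone; adjusted p = 0.61). The list of 9 genes used as strain markers was not called either, though 4 of its genes were higher in the C-limited mutant at low inositol-choline (adjusted p = 0.077), LYS2 at 0.34 and HIS3 at 0.31.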
